A study of Homo sapiens with 12 samples.

How the data were processed

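The samples were 12 iCLIP libraries from H9 cells, an established human embryonic stem cell line. iCLIP joins a protein to the RNA it touches with ultraviolet light, recovers the protein with an antibody and sequences the RNA fragments, so that the end of each cDNA marks the crosslinked nucleotide. Per the labels, wild-type (WT) and P-KO cells were crosslinked at 400 mJ per square centimetre, and RNA was recovered with antibodies against 3 RNA-binding proteins: RBFOX2 (written FOX2 here), TDP43 and hnRNP M. Each protein and genotype had 2 libraries, which the series design text calls biological replicates. Groups and replicate numbers were taken from the sample labels.

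Per the submitters' processing notes, reads were aligned with Bowtie to the human build GRCh37 (hg19); the Bowtie version and the peak caller are not given in the sources used here. The authors deposited one list per library, each line being 1 nucleotide with an Ensembl transcript, an intron number where the position is intronic, a strand, a whole-number count and a p-value or q-value. Which of p and q the last column holds is not stated, and it is called q here; it was never above 0.05. The authors' deposited counts are not normalized, and whether they are reads or cDNAs collapsed by their random barcodes is not stated. The lowest listed count was 2. Because values under these limits are left out, a bin without a line is described as listed at 0, with no upper limit and no fold.

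Pairs of listed positions standing alone and up to 5 nt apart carried equal counts in 95.1% to 100% of cases per library, which is how it was read from the values that each count covers 5 nt on both sides, a window of 11 nt. Pairs 6 to 60 nt apart were equal in 37.3% to 83.3% of cases in FOX2 and TDP43 libraries and 13.2% to 25.7% in hnRNP M. The contrast was thus clearest in the hnRNP M libraries. Counts of overlapping windows cannot be added. Windows were therefore kept from the highest count downwards, with at least 11 nt between kept positions on a strand, and their counts are called window counts. This step was chosen after the files were examined. Window counts per library ranged from 58191 to 648651, a ratio of 11.1. Replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom of 5.99 in FOX2 WT and 7.15 in FOX2 P-KO, so no library was treated as a duplicate.

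No gene annotation of hg19 was used here, and the transcript identifiers could not be paired with gene names. The planned fallback was used: strand-specific 10 kb bins took the place of genes. Signal fell in 97622 bins. edgeR 4.0.16 in R 4.3.3 was run on window counts per bin with filterByExpr, TMM normalization and the quasi-likelihood F test at its default settings; 10563 bins were tested and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All 12 libraries shared one fit with a mean per protein and genotype. The effect common to the 3 proteins was tested with protein as an additive term, and differences of the genotype effect between proteins with an F test of the interaction. The common dispersion corresponded to a biological coefficient of variation of 1.09. The robust option of edgeR was fitted first during exploration, and the default was kept after the results of both had been seen; the counts of both are given in the closing section. TMM factors ranged from 0.373 in FOX2 P-KO replicate 2 to 3.24 in hnRNP M WT replicate 1, and the comparisons between proteins were repeated without them. DESeq2 1.42.0 was an alternative.

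The share of window counts in the region 25000001 to 26000000 of chromosome 15, plus strand, was compared by an exact permutation test on log2 shares, two-sided, with genotype permuted within each protein (smallest possible p 0.00926). Intron shares were tested in the same way. Exact Clopper-Pearson intervals at 95% cover counting error only and treat each count as independent, so they are too narrow where counts are copies of one another. Overlap of 2 libraries was the percentage of windows of the smaller set that shared at least 1 nt with a window of the other. CPM values are window counts per 1000000 window counts of a library. Correlations were Pearson's r across bins, which are not independent replicates. Python 3.11.15 with scipy 1.17.1 was used for these steps.

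The bins named were chosen by a rule written before the data were examined: for each comparison, the largest rises and falls among bins past the threshold whose groups did not overlap and whose mean count in the higher group was at least 10 (for the common effect, bins moving the same way in all 3 proteins); the 10 bins of smallest p, called not passing, where fewer than 5 passed; the bins of the chromosome 15 region; and the 10 bins of highest share per protein in WT. The fits were tested on simulated counts drawn from these libraries' means and spread, run on 8040 bins. The lowered bins were drawn at random from those with an expected count of at least 1 in each protein at median depth. The rates therefore need not hold for bins with high counts. Of 60 bins lowered 64-fold in P-KO, the fit of the common effect called 20 (and 1 unchanged bin), the FOX2 comparison 1, and the TDP43 and hnRNP M comparisons 0. Of 55 bins lowered 16-fold, the fit of the common effect called 8 and the comparisons of single proteins 0. The comparisons of single proteins can therefore miss large changes in bins drawn this way.

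Alternatives were other normalizations, filters, units of signal and designs, a replicate block and leaving out each library. Tests of sequence motifs need a genome of the build, and tests of gene lists need gene names; neither was run. Positions were split into intron and other only, since coding and untranslated exons were not told apart. The planned anchors of the region at annotated genes were replaced by the planned coordinates above.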

Results

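The study asked where FOX2, TDP43 and hnRNP M contact RNA in H9 cells, and what changes in P-KO cells, whose source label carries the name SPA. SPA RNAs are long noncoding RNAs from the Prader-Willi region of chromosome 15 that begin with a small nucleolar RNA and end in a poly(A) tail; this is background knowledge and is not measured here. FOX2 is a splicing factor that binds GCAUG-like elements, TDP43 binds GU-rich RNA, and hnRNP M is an abundant nuclear RNA-binding protein. The 12 libraries held 1162690 listed positions. Window counts were 218733 and 288698 in the FOX2 WT libraries, 232174 and 648651 in FOX2 P-KO, 207788 and 282997 in TDP43 WT, 172613 and 292694 in TDP43 P-KO, 61625 and 123482 in hnRNP M WT, and 62030 and 58191 in hnRNP M P-KO. The hnRNP M libraries were the shallowest, so the counting error of a given share is largest there.

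The region of chromosome 15 from 25000001 to 26000000 (hg19, plus strand) was compared first, since it checks the genotype labels. In WT cells it held 1.505% ± 0.178 (SD, n = 2) of FOX2 window counts, 1.11% ± 0.278 of TDP43 counts and 1.36% ± 0.213 of hnRNP M counts. In P-KO cells the shares were 0.101% ± 0.0263, 0.0618% ± 0.0125 and 0.137% ± 0.0314. The WT share was 14.9 times the P-KO share for FOX2, 18.0 times for TDP43 and 9.94 times for hnRNP M. Over the 3 proteins the log2 share fell by 3.80 (exact stratified permutation test, two-sided, p = 0.00926, the smallest the arrangements can give), and the share was lower in each P-KO library than in every WT library. Within a single protein, 2 libraries against 2 cannot give an exact p under 0.333. The windows behind these shares covered 3751 and 4455 nt in FOX2 WT against 506 and 1507 nt in FOX2 P-KO, 3278 and 3718 nt against 495 and 649 nt for TDP43, and 1111 and 3454 nt against 132 and 132 nt for hnRNP M. The mean count per window was 8.84 and 11.6 in FOX2 WT against 4.15 and 5.66 in FOX2 P-KO, and 9.12 and 7.66 against 2.71 and 2.63 for TDP43. For hnRNP M it was 9.25 and 4.77 in WT and 8.25 and 5.58 in P-KO, close to the means of the whole libraries (8.44, 3.81, 7.86 and 5.07). In all 3 proteins most WT windows lay in the span named below and most P-KO windows outside it. The means therefore compare different sites, and how the loss divides between windows and counts per window cannot be read from them. The lowest WT share was 0.915% in TDP43 WT replicate 2 (95% Clopper-Pearson interval 0.880 to 0.951), and the highest P-KO share was 0.160% in hnRNP M P-KO replicate 1 (0.130 to 0.194). The latter rests on 99 counts in 12 windows, and its interval treats each count as independent, so it may be too narrow.

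**Figure D1:**
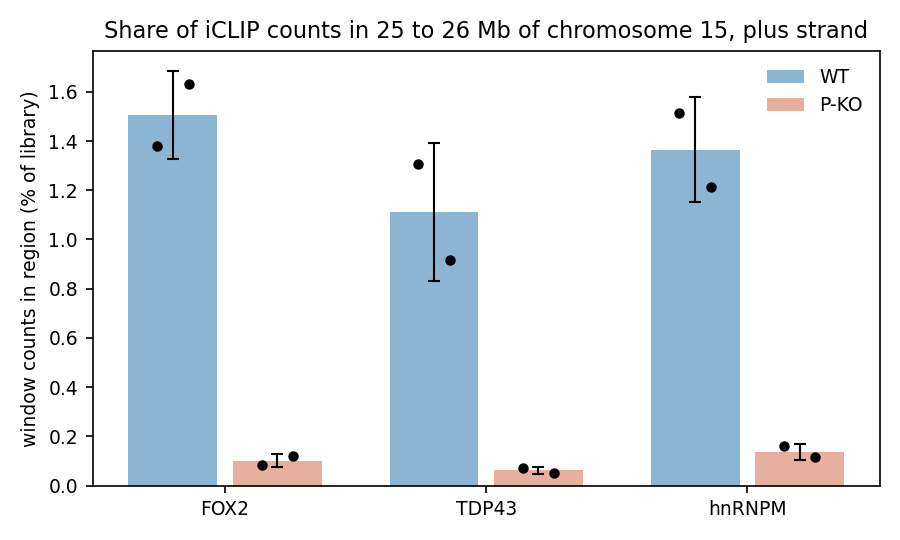
Window counts between 25 and 26 Mb of chromosome 15, plus strand, as a percentage of each library's window counts (y axis), by protein (x axis) and genotype. Bars are means of 2 libraries, points are libraries and error bars are 1 SD; each P-KO library lies at or under 0.160% and each WT library at or above 0.915%.

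Most of the lost signal lay in one stretch. In the test of the effect common to the 3 proteins, 13 of 10563 bins passed and all 13 fell in P-KO. Of these, 12 lay on the plus strand of chromosome 15 between 25230001 and 25360000. The span held 1.35% ± 0.188 of FOX2 counts in WT and 0.0110% ± 0.0143 in P-KO, and 0.928% ± 0.273 of TDP43 counts in WT and 0.00790% ± 0.00380 in P-KO. It held 1.23% ± 0.210 of hnRNP M counts in WT, and both hnRNP M P-KO libraries were listed at 0 there. The smallest adjusted p in the edgeR quasi-likelihood test, 7.03e-10, was shared by the bin at 25260001 to 25270000 and the bin at 25270001 to 25280000, both of which were listed at 0 in all 6 P-KO libraries. The other falls had adjusted p from 4.74e-09 to 0.00548 within the span. The bin at 25340001 to 25350000 lies inside the span and did not pass (adjusted p = 0.533 by edgeR). Of the 20 tested bins of the region, 1 of them on the minus strand, 15 passed in the common test when adjusted over the list alone, all lower in P-KO.

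The remaining bin past the threshold lay on the minus strand of chromosome 3, from 75820001 to 75830000, with 100% of its counts in introns. It had 93 and 83 counts in the FOX2 WT libraries and was listed at 0 in the other 10 libraries, so it does not move the same way in all 3 proteins (edgeR adjusted p = 0.0486). It is therefore outside the rule for named bins of the common effect, but is named by the rule for FOX2 among the 10 bins of smallest p, as not passing (adjusted p = 0.110 by edgeR). The bin did not pass in the common test with the robust option, the 3 nt batch term, a minimum of 20 counts in 2 libraries, without mitochondrial and GL000220 positions, or without any one FOX2, TDP43 or hnRNP M P-KO library, where each call lay in the region. With DESeq2, 13 of 15 calls lay in the region, and 2 of the 15 were higher in P-KO. It passed in an edgeR fit of the FOX2 libraries alone (adjusted p = 0.0184). The test of the common effect called 8 bins without FOX2 P-KO replicate 1.

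Some bins next to the span had signal in P-KO cells. The bin at 25200001 to 25210000 had 82 and 124 counts in FOX2 WT and 110 and 415 in FOX2 P-KO, and 0 and 31 in hnRNP M WT against 46 and 25 in hnRNP M P-KO (edgeR adjusted p = 1.00 for the common effect). The bin at 25220001 to 25230000, just before the span, had 286 and 369 counts in TDP43 WT and 20 and 20 in TDP43 P-KO, but did not pass over all bins (adjusted p = 0.340 by edgeR, 0.000694 adjusted over the list alone). Just after the span, the bin at 25360001 to 25370000 had 39 and 18 counts in FOX2 WT and was listed at 0 in FOX2 P-KO. TDP43 had 72 and 49 there in WT and 5 and 0 in P-KO, and hnRNP M 0 and 14 against 10 and 0. This bin did not pass over all bins either (adjusted p = 0.4415 by edgeR, 0.000955 adjusted over the list alone). On the part of the region before the span, FOX2 held 0.138% in WT and 0.0837% in P-KO, TDP43 0.147% and 0.0397%, and hnRNP M 0.0952% and 0.110%. The exact permutation p for this part was 0.0463, and for the part after the span it was 0.0556. In FOX2 and TDP43 most WT counts before the span lay in the bin at 25220001 to 25230000. It held 180 and 255 of 301 and 400 counts in FOX2 WT, and 286 and 369 of 307 and 416 in TDP43 WT. In P-KO it held 34 and 73 of 183 and 575 for FOX2, and 20 and 20 of 81 and 95 for TDP43. The tested bins at 25200001 and 25210001 had common log2 fold changes of 0.884 and 0.364 and did not pass. The fall of this part therefore need not hold over its whole length. The bounds of the span were chosen from the calls themselves.

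FOX2 and TDP43 had their highest bins at different places along the span in WT cells. FOX2 counts gathered in the bin at 25310001 to 25320000, with 8009 ± 1822 window counts per 1000000 window counts of the library (CPM; SD, n = 2), which was 55.1% and 62.6% of the counts of the span in the 2 libraries. TDP43 had 418 ± 224 CPM there and was highest in the bin at 25230001 to 25240000 (3365 ± 1156) and the bin at 25260001 to 25270000 (2893 ± 1048). hnRNP M counts were spread over several bins with no single highest one in both libraries, with 2071 ± 215 CPM at 25330001 to 25340000, 2014 ± 25.98 at 25310001 to 25320000 and 1796 ± 352 at 25290001 to 25300000. The highest FOX2 window in WT replicate 2 was at 25312026, in intron 4 of ENST00000549804.2, with 93 counts. It had 20 counts in FOX2 WT replicate 1, 0 in FOX2 P-KO replicate 1 and 5 in FOX2 P-KO replicate 2. The highest TDP43 window in WT replicate 2 was at 25231845, in intron 5 of ENST00000557230.1, with 49 counts, 13 in the other TDP43 WT library and 0 in both TDP43 P-KO libraries. FOX2 WT also had 12 and 17 counts at this window. In the edgeR tests between proteins in WT, 0 bins of the region passed in any of the 3 comparisons, also when adjusted over the list alone, with 1119, 1922 and 1731 bins outside the region at an unadjusted p under 0.05; DESeq2 called 3, 1 and 4 bins of the region. Other edgeR settings also called some: 3 for FOX2 against TDP43 in a fit of these libraries alone, 1 each for FOX2 and TDP43 against hnRNP M with a replicate block, and 4, 4 and 3 by the number of windows per bin.

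**Figure D2:**
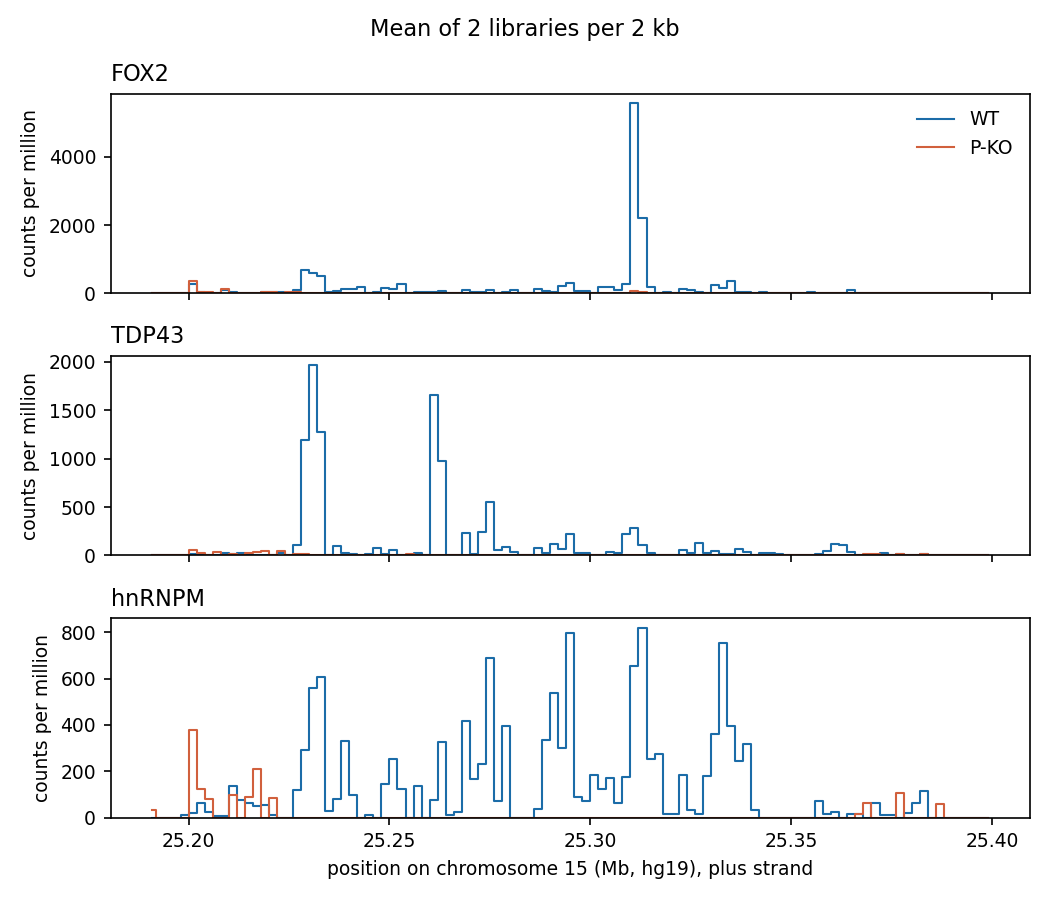
Window counts as CPM in steps of 2 kb (y axis, different scale per panel) along the plus strand of chromosome 15 (x axis, Mb, hg19) for each protein, as the mean of 2 libraries, WT in blue and P-KO in orange. FOX2 is highest after 25310001, TDP43 after 25230001 and 25260001, and the WT signal of the span is nearly missing in P-KO.

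For single proteins, few bins passed at the default settings, and these lay in the span. FOX2 had 2 bins lower in P-KO. The bin at 25300001 to 25310000 had 730 ± 418 CPM in WT and was listed at 0 in both P-KO libraries (edgeR adjusted p = 0.0245); the bin at 25240001 to 25250000 had 498 ± 13.5 and was also listed at 0 (adjusted p = 0.0488 by edgeR). The FOX2 bin with the most signal, at 25310001 to 25320000, had 1470 and 2684 counts in WT and 0 and 102 in P-KO and did not pass (adjusted p = 0.336 by edgeR). Of the 20 tested bins of the region, 14 passed in FOX2 when adjusted over the list alone, all lower. The FOX2 count is unstable: it was 0 without any one of the 8 FOX2 and TDP43 libraries, 9 without either hnRNP M WT library, 11 with DESeq2 and 0 with the robust option of edgeR.

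TDP43 had 3 bins lower in P-KO. The bin at 25260001 to 25270000 had 755 and 609 counts in WT and was listed at 0 in both P-KO libraries (edgeR adjusted p = 0.00285). The bin at 25270001 to 25280000 had 964 ± 589 CPM in WT and was listed at 0 in P-KO (edgeR adjusted p = 0.0193). The bin at 25230001 to 25240000 had 869 and 721 counts in WT and 0 and 4 in P-KO (edgeR adjusted p = 0.0294). Of the 20 bins of the region, 13 passed when adjusted over the list alone. Leaving out any one FOX2 or TDP43 library gave 0 or 1 bins, DESeq2 gave 7, and the robust option of edgeR gave 1.

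hnRNP M had 5 bins lower in P-KO, each listed at 0 in both P-KO libraries: those starting at 25310001, 25330001, 25290001 and 25270001 (edgeR adjusted p = 0.0253 for each) and at 25230001 (adjusted p = 0.0394 by edgeR). The bin at 25270001 to 25280000 had 1556 ± 20.9 CPM in WT, and the bin at 25230001 to 25240000 had 1610 ± 868. Of the 20 bins of the region, 11 passed when adjusted over the list alone. The count was 0 without any one FOX2 or TDP43 library or either hnRNP M P-KO library, 10 without hnRNP M WT replicate 1, 30 with DESeq2, of which 5 were higher in P-KO, and 0 with the robust option of edgeR. The hnRNP M libraries also carried high counts at isolated positions, with a most frequent count of 9 in both replicate 1 libraries against 2 in FOX2 and TDP43.

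Outside the region, 0 bins passed in the edgeR comparison of any single protein at the default settings. At an unadjusted p under 0.05 there were 379 bins outside it for FOX2, 206 for TDP43 and 1214 for hnRNP M. Over all tested bins this p was reached by 3.72% for FOX2, 2.07% for TDP43 and 11.6% for hnRNP M. Without any effect a fraction of 0.05 would reach it, which only hnRNP M exceeded in this joint fit. The order was not kept in edgeR fits of each protein's libraries alone. There 361 of 3956 bins reached it for FOX2, 94 of 4124 for TDP43 and 23 of 693 for hnRNP M, and only FOX2 exceeded that fraction. Of the bins outside the region in the joint fit, 59 were higher and 320 lower in P-KO for FOX2, 155 and 51 for TDP43, and 336 and 878 for hnRNP M. With DESeq2, the bins past the threshold were 11 for FOX2 and 7 for TDP43, all in the region, and 30 for hnRNP M, of which 11 were in the region. Other edgeR settings called bins outside it. For FOX2 these were 1 of 9 with the FOX2 libraries alone (the bin on chromosome 3), 1 of 10 without TMM, 1 of 10 with a replicate block, 1 of 8 with windows at or above the median count, 3 of 16 by the number of windows and 1 of 9 without either hnRNP M WT library. For hnRNP M they were 1 of 9 with a replicate block and 1 of 10 without hnRNP M WT replicate 1. The bin at 174250001 to 174260000 on the minus strand of chromosome 4 had 50 and 26 counts in TDP43 WT and was listed at 0 in TDP43 P-KO, without passing. The bin at 8700001 to 8710000 on the minus strand of chromosome 18, also not passing, was listed at 0 in TDP43 WT and had 56 and 0 counts in TDP43 P-KO. No difference of the genotype effect between the proteins passed: the edgeR interaction test called 0 bins, with 524 at an unadjusted p under 0.05, and DESeq2 also called 0. The interaction was not among the simulated fits, and bins listed at 0 in all P-KO libraries cannot show it. The 0 calls therefore do not show that the effects were equal.

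Between proteins in WT cells, the edgeR test called 30 bins for FOX2 against TDP43, of which 26 were higher in FOX2 and 4 in TDP43. The split was more even in some settings, with 266 and 149 by DESeq2, 381 and 188 in an edgeR fit of these libraries alone, and 239 and 199 by the number of windows. It was more one-sided in others, with 58 and 4 for intron positions only and 50 and 5 with the 3 nt batch term. Without mitochondrial and GL000220 positions it was 34 and 4. The bin at 20790001 to 20800000 on the plus strand of chromosome 18 had 134 and 433 counts in FOX2 WT and was listed at 0 in TDP43 WT (edgeR adjusted p = 0.0202). The bin at 47730001 to 47740000 on the minus strand of chromosome 19 went the other way, with 132 and 162 counts in TDP43 WT and none listed in FOX2 WT (adjusted p = 0.0314 by edgeR). FOX2 against hnRNP M gave 278 bins, all higher in FOX2. This direction was not kept throughout: without TMM 76 were higher and 6 lower in FOX2, by the number of windows 255 and 65, and with DESeq2 604 and 14. The bin at 168200001 to 168210000 on the plus strand of chromosome 2 had 1178 ± 73.6 CPM in FOX2 WT and was listed at 0 in hnRNP M WT (edgeR adjusted p = 0.00754). TDP43 against hnRNP M gave 11 bins, all higher in TDP43, against 15 higher and 1 lower without TMM, 125 and 24 by the number of windows, and 459 and 22 with DESeq2. Among the 11, the bin at 98470001 to 98480000 on the plus strand of chromosome 7 had 1295 and 521 counts in TDP43 WT and was listed at 0 in hnRNP M WT (edgeR adjusted p = 0.00185). These counts moved strongly with the libraries and the tool: the first was 0 without any one FOX2 or TDP43 library and 415 with DESeq2, the second 0 without FOX2 P-KO replicate 1, either FOX2 WT library or hnRNP M WT replicate 1, and the third 0 without FOX2 WT replicate 1, 1 or 2 without any other FOX2 or TDP43 library or hnRNP M WT replicate 1, and 481 with DESeq2.

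The bins with the highest share in WT were in part shared by the 3 proteins, since GL000220 and the mitochondrial bin were among the 3 highest of each. The highest FOX2 bins were the ribosomal contig GL000220 (1.60% ± 0.825 of FOX2 counts), the region's bin at 25310001, the mitochondrial bin (0.735% ± 0.554) and the bin at 980001 to 990000 on the plus strand of chromosome 1 (0.343% ± 0.147). They were followed by 0.287% at 93530001 to 93540000 on the minus strand of chromosome 5, where TDP43 had 0.00467%. TDP43 had 3.36% ± 0.595 of its counts in the bin at 109640001 to 109650000 on the plus strand of chromosome 1, against 0.131% of FOX2 and 0.0373% of hnRNP M counts, followed by GL000220 (3.27% ± 1.90), the mitochondrial bin (2.39% ± 1.76) and 0.8415% at 65270001 to 65280000 on the plus strand of chromosome 11. hnRNP M was highest on average at GL000220 (1.45% ± 1.71) and the mitochondrial bin (1.30% ± 1.37), and 5 of its 10 highest bins lay in the span. These 2 means were set mostly by WT replicate 2: GL000220 had 0.242% in replicate 1 and 2.67% in replicate 2, and all mitochondrial positions 0.404% and 2.36%.

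Mean correlation between libraries was higher within than between proteins, clearly for FOX2 and TDP43. For hnRNP M the ranges overlapped, with 0.0938 to 0.1925 between its libraries and up to 0.1462 with TDP43 libraries. The count filter keeps bins that are high in 1 protein alone, which can raise r within that protein and lower it between proteins. Pearson's r across tested bins averaged 0.6345 between FOX2 libraries of one genotype and 0.579 between genotypes, 0.519 and 0.522 for TDP43, and 0.150 and 0.141 for hnRNP M. For FOX2 the WT pair had 0.535 and the P-KO pair 0.734, while pairs of different genotypes ranged from 0.532 to 0.660. Between proteins it averaged 0.0940 for FOX2 and TDP43, 0.00466 for FOX2 and hnRNP M, and 0.0342 for TDP43 and hnRNP M. Replicates of one genotype shared 15.6% of windows in FOX2, 7.09% in TDP43 and 1.04% in hnRNP M, and libraries of different genotypes 12.6%, 7.30% and 1.14%. The FOX2 mean joins 6.80% for the WT pair, lower than any pair of a FOX2 WT and a FOX2 P-KO library (11.47% to 15.03%), and 24.4% for the P-KO pair. Between proteins the overlap averaged 2.33% for FOX2 and TDP43, 2.10% for FOX2 and hnRNP M and 1.85% for TDP43 and hnRNP M. These percentages grow with the size of the larger set, which was 57236 to 112599 windows in FOX2 and TDP43 libraries and 7299 to 32394 in hnRNP M, so overlaps within and between proteins are not compared here. The difference between within and between genotypes was below the SD over pairs of libraries for each protein (5.93, 1.30 and 0.646 percentage points).

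**Figure D3:**
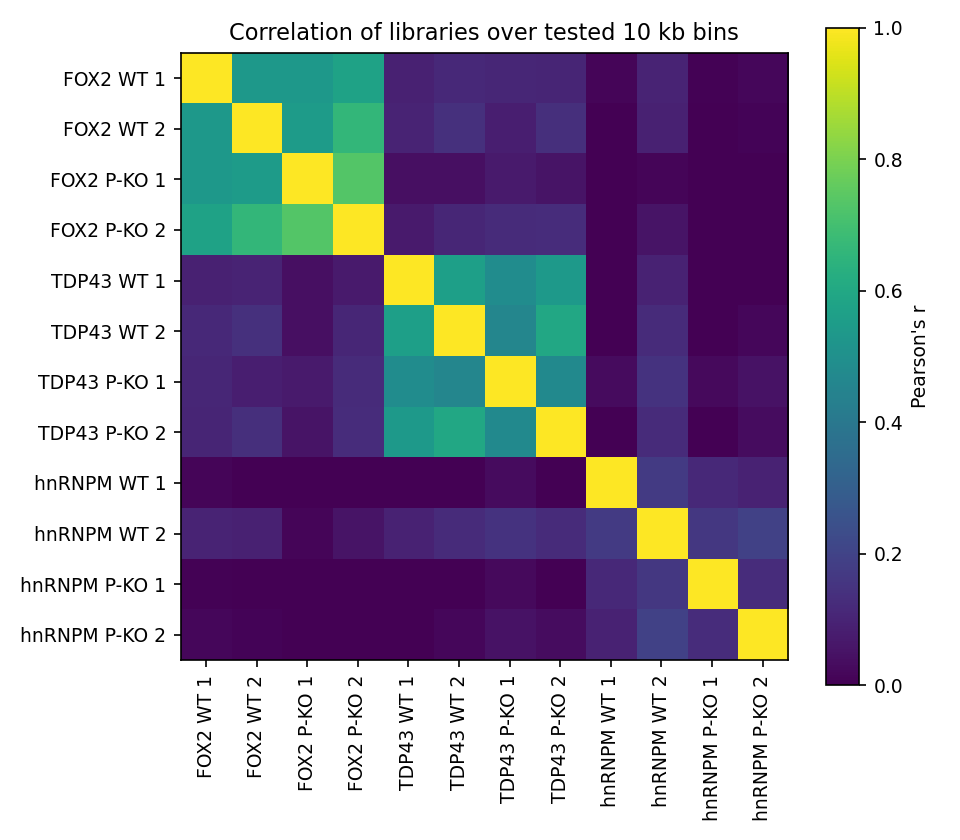
Pearson's r between libraries over tested 10 kb bins, on log2 of TMM-normalized CPM plus 10, colour scale from 0 to 1 with values under 0 drawn as 0. FOX2 and TDP43 libraries form blocks by protein, and the hnRNP M libraries correlate weakly with each other.

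Introns held most counts in every library: 88.5% ± 1.53 in FOX2 WT and 84.9% ± 0.915 in P-KO, 82.0% ± 3.18 and 86.0% ± 5.19 for TDP43, and 91.5% ± 4.73 and 93.1% ± 3.13 for hnRNP M. The difference over the 3 proteins was 0.700 percentage points higher in P-KO and did not hold up against the spread (exact stratified permutation p = 0.741).

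The hnRNP M libraries stood apart in the counts at positions with no other listed position within 200 nt. The most frequent count there was 2 in each FOX2 and TDP43 library, and 9, 3, 9 and 5 in hnRNP M WT replicates 1 and 2 and P-KO replicates 1 and 2. Such counts enter every hnRNP M comparison.

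**Figure D4:**
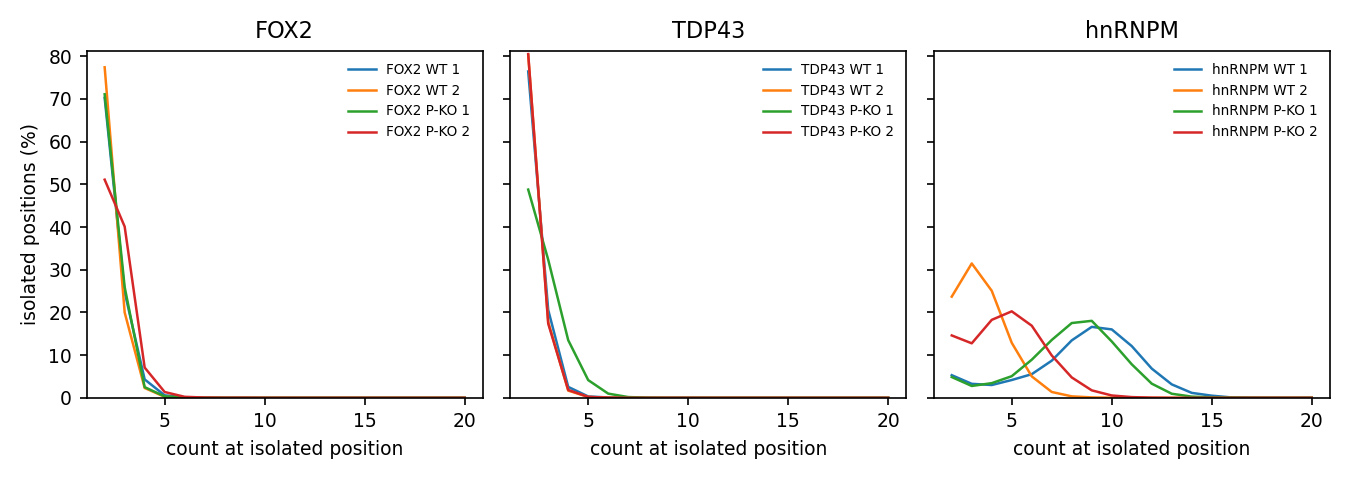
Percentage of isolated positions (y axis) by their count (x axis, 2 to 20), one line per library. The lines peak at 2 in the FOX2 and TDP43 libraries and at 9, 3, 9 and 5 in the hnRNP M libraries.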

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

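Several alternatives were chosen after seeing the data: transcripts in place of bins, all listed positions summed, the 3 nt batch term, leaving out mitochondrial and GL000220 positions, leaving out hnRNP M libraries together, and the robust option of edgeR. The robust option had been fitted first, and the default was kept after both had been seen. The fall of the region's log2 share held its direction and its side of the threshold under each alternative that gave a value, from -2.63 (share of windows) to -4.79 (all listed positions summed), and from -3.71 to -3.89 without any one library. With a replicate block it was -3.80 (exact permutation p = 0.0313, the smallest the block allows). The common effect, 13 bins, gave 9 to 17 under the alternatives except 6 with transcripts in place of bins and 0 with the region left out, and 8 (without FOX2 P-KO replicate 1) to 15 without any one library. With DESeq2 it gave 15 bins, of which 2 were higher in P-KO; 1 bin was higher by the number of windows, without hnRNP M WT replicate 1, without both hnRNP M replicate 1 libraries and without the hnRNP M libraries. The interaction count was 0 under each alternative run, but how large a difference this test could find was not simulated. There were 54 named results, each a bin in 1 comparison, so the same bin can enter under several comparisons. Of 1419 alternatives for them, 1042 held direction and side of the threshold, 305 lost the call, 72 gained it and 0 reversed. Results named as not passing count as held where they stayed uncalled. Alternatives in which the filter dropped the bin or no fold change was left are not counted.

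The counts for single proteins moved more, and apart from the constructions named here the cause was not tested. They are given for FOX2 (2 bins), TDP43 (3) and hnRNP M (5) in this order. DESeq2 gave 11, 7 and 30, a replicate block 10, 6 and 9, and only libraries of the proteins compared 9, 0 and 0 (unadjusted p under 0.05 in edgeR: 361 of 3956, 94 of 4124 and 23 of 693 bins). All listed positions summed gave 0, 1 and 0, the robust option 0, 1 and 0 (unadjusted 386, 198 and 1100), and the region left out 0, 0 and 0, since each call lay in the region. A minimum of 20 counts in 2 libraries gave 6 for FOX2 and 0 for hnRNP M, and no count filter 2 for hnRNP M. For FOX2, library totals without TMM gave 10, windows at or above the median count 8, transcripts 4 and the 3 nt batch term 0. The number of windows per bin gave 16 for FOX2 and 8 for TDP43. Without any one library the counts ranged from 0 to 9 for FOX2, 0 to 4 for TDP43 and 0 to 10 for hnRNP M. Where a group is left with 1 library, that library is assumed to vary like the other groups, and the filter keeps more bins.

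Between proteins in WT, the counts are given for FOX2 against TDP43 (30), FOX2 against hnRNP M (278) and TDP43 against hnRNP M (11), and the cause was not tested. DESeq2 gave 415, 618 and 481, only libraries of the proteins compared 569, 140 and 0, transcripts 77, 87 and 24, the robust option 0, 87 and 1, no count filter 10, 61 and 6, and a minimum of 20 counts in 2 libraries 5, 98 and 2. Library totals without TMM gave 138 and 82 for the comparisons of FOX2 with TDP43 and hnRNP M. For FOX2 against TDP43 and TDP43 against hnRNP M, a replicate block gave 152 and 248, windows at or above the median count 169 and 68, the number of windows per bin 438 and 149, thinning 145 and 69, and the 3 nt batch term 55 and 17. For FOX2 against TDP43, intron positions only gave 62 and all listed positions summed 1. Without any one library the counts ranged from 0 to 187, 0 to 372 and 0 to 115.

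The intron difference of 0.700 percentage points reversed to -0.196 as a share of windows and ranged from -0.524 to 1.92 without any one library; with a replicate block its exact permutation p was 0.688. The overlap difference within minus between genotypes ranged, without any one library, from -6.46 to 12.8 percentage points for FOX2, -1.79 to 2.07 for TDP43 and -1.13 to 0.520 for hnRNP M. Here too the cause was not tested.

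The hnRNP M libraries hold the fewest window counts, 58191 to 123482. In simulated data, 64-fold falls were called in 1 of 60 bins for FOX2 alone and in 0 of 60 for TDP43 and for hnRNP M alone, so which protein is limited most was not shown. Not run were motif tests, tests of gene lists, the whole Prader-Willi region, a denominator within genes only, both strands for transcript regions, a crossed pairing (no correlation of numbers was negative enough to call for it) and the share of the called span only, where libraries listed at 0 give no log value.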

Other observations

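The tests in this part were chosen after the results they bear on had been seen, except thinning, which was chosen before the data were examined.

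Other bins with a high share of signal in WT cells differed between the proteins, as values without a test. FOX2 had 0.238% ± 0.0264 (SD, n = 2) of its counts at 63350001 to 63360000 on the plus strand of chromosome 15, where TDP43 had 0.0309% and hnRNP M 0.0235%, and 0.211% ± 0.0577 at 38270001 to 38280000 on the minus strand of chromosome 8. TDP43 had 0.359% ± 0.0418 at 160230001 to 160240000 on the minus strand of chromosome 3, against 0.0264% of FOX2 counts, with 99.9% of the counts of that bin in introns. hnRNP M had 0.211% ± 0.0433 at 93680001 to 93690000 on the minus strand of chromosome 5, where its P-KO libraries had 0.240% ± 0.0409. In WT, FOX2 had 0.143% at this bin, nearer to hnRNP M than the 0.0175% of TDP43.

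The fall of the span on chromosome 15 was weighed against 3 technical explanations. Chance assignment of libraries is argued against: 1 of 100 drawn splits within proteins, the real one, called 13 bins, and the highest of the others called 7. The calls of the splits were counted over all tested bins, not over the span alone. If unequal depth were the cause, the calls should be lost when libraries are thinned to the smallest of their protein, but 12 bins of the region were still called. The listing limits were not applied again after thinning. Windows that fall under these limits in shallower libraries were therefore not covered by this check. An excess of listed positions 3 nt apart was seen in 5 of the 12 libraries, all of them replicate 2, and was taken as a possible sign of a library batch. The sample labels used here name no batch. Relative to the mean of pairs 2 and 4 nt apart, the excess was 3.42 to 4.28 in FOX2 and TDP43, and 37.7 and 73.1 in hnRNP M. That it marks 1 shared batch was not shown. In TDP43 and hnRNP M the excess fell on both genotypes, so it was balanced there, and in FOX2 on WT only. With a term for it in the fit, 12 bins of the region were still called in the common test. Since the excess was balanced in 2 of the proteins, this says little beyond FOX2, where the calls of FOX2 alone went from 2 to 0. What stays open is the source of the loss: RNA that is not made in P-KO cells and RNA that is made but not bound may both leave these counts, and no RNA level was analysed here.

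The high counts at isolated positions in hnRNP M libraries may come from amplified copies of few cDNAs. Among windows of 9 or more counts, 96.3% in hnRNP M WT replicate 1 and 96.9% in P-KO replicate 1 held 1 listed position, against 8.93% at most in a FOX2 or TDP43 library, and at most 0.537% of these single-position windows recurred in the other replicate 1 library. The overlap of these 2 libraries over all their windows was also low, at 0.603%. The low recurrence therefore does not set the single-position windows apart and was not read as evidence of copies. A minimum set by the authors' q filter is argued against: positions near such a minimum should carry q above 0, but the highest share of isolated positions with q above 0 was 19.2% in hnRNP M against a lowest of 41.7% in the other proteins. Sharp sites that differ between cultures stay open and were not tested. The bins of the span fell in hnRNP M P-KO replicate 2 as well, where 51.3% of such windows held 1 position, against 17.5% in WT replicate 2.

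FOX2 P-KO replicate 2 kept 102 counts in the bin at 25310001 to 25320000, 74.5% of its counts in the span, while replicate 1 had 0. RNA at an equal level in both cultures would give 36.5 counts in replicate 1 at its depth, but spread over 18 windows at 2.03 counts each, next to the listing minimum of 2, so the listed 0 does not exclude it. Carry-over of FOX2 WT material could give the same profile; it would give 4.32 counts in the bin on chromosome 3 that only FOX2 WT covers, where 0 were listed, which are too few above that minimum to decide. These explanations and a difference between the cultures, which was not tested, cannot be told apart here.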
